A study of Mus musculus with 9 samples.

How the data were processed

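MicroRNA (miRNA) was measured in the olfactory bulb of 8-week-old male ICR mice, an outbred strain, on 9 single-colour arrays: 3 of control mice, 3 of mice exposed to formaldehyde for 1 day (FA 1 day) and 3 of mice exposed for 7 days (FA 7 days). Formaldehyde is an irritant gas, given here in a chamber at 3 ppm for 6 hours per day, and the control mice were kept the same way without it. The labels do not give the time at which the control mice were dissected, nor slides or scan days, so no batch was tested. Total RNA was labelled at its 3' end with the dye Hy3 from an Exiqon miRCURY kit and hybridised to Exiqon probes, per the labels' protocols. The groups and replicate numbers were taken from the labels, which number the FA 1 day samples 1, 2 and 4. The labels do not state that each array holds a separate animal, and the p-values then measure only the spread between these samples.

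The deposited raw table gives, per the file headers, the foreground intensity and the foreground minus background intensity of 12312 spots on each array. These cover 2673 probes, of which 1027 are named as mouse miRNAs (median of 4 spots each), 57 as miRNAs of mouse viruses and 61 as spike-in controls, while 1495 have no name in the table. The scanner and image software are not given in the sources used here. The authors also deposited a value table in the form of a ratio. Set against the raw table, each of its columns matched, within 1% for 100% of the listed values, the median over a probe's spots of foreground minus background divided by 1 factor per array, that array's median over the 301 miRNA probes of at least 50 on all arrays; values at or under 0 are blank. This settles its scale (linear), its centring (on that factor) and its direction. Its column medians run from 0.0196 to 0.16, and 19 to 1319 probes per array are blank. All columns of per-sample values in both tables were matched to a sample by name.

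From the raw table, the background was corrected per spot with limma's normexp method (offset 50, R 4.3.3, limma 3.58.1), spots of a probe were averaged, and arrays were quantile normalized over the 1084 probes named as miRNAs, followed by log2. Quantile normalization makes the distribution of the miRNA probes equal on all arrays, so a shift shared by most miRNAs cannot be seen, and it gives the brightest probe, miR-124-3p, the same value on every array. A probe counted as detected on an array at foreground minus background of at least 30. Tested were the 462 mouse probes detected on every array of at least 1 group, 14 of which name more than 1 mouse miRNA; such a probe is named by its first. The unnamed, viral, spike-in and other control probes stayed out of the tests. Values of the unnamed, spike-in and other control probes were placed on each array by the curve that normalization gave its miRNA probes. Names are those of the array's design. Since the files name no genome build, no coordinates are given.

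Median background ran from 35 to 49 per array and the median foreground minus background of the 351 mouse probes detected on all arrays from 224 to 441. On these arrays the number of arrays limits the precision: at the median standard error of 0.27 (log2) a 95% interval reaches 0.62 to either side of a difference. No pair of arrays held the same foreground value at more than 10.7% of the spots, so all 9 were kept as separate samples.

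A group-means model was fitted with limma (lmFit and eBayes) to all 9 arrays, with 3 pairwise comparisons and a moderated F-test over the 3 groups, two-sided, with Benjamini-Hochberg adjustment over the 462 probes and a threshold of 0.05. The 16 lists of miRNAs, described with the results, were tested with camera at a preset correlation of 0.01, adjusted over the 16 lists in each comparison; camera compares a list with all other probes. An estimated correlation and fry, which tests whether a list's probes move one way on balance and compares them with no others, were alternatives. The lists share from 0 to 9 members with other lists. The agreement of the 2 exposures was set against 100 simulations of unchanged groups sharing their controls, made from random mixes of the arrays' residuals. Named in the text are, for each comparison, the 12 higher and 12 lower probes with the smallest unadjusted p, given as values only where they did not pass the threshold. The rule for naming also took, of each list, the members past the threshold or otherwise the 2 with the smallest p; the text gives these for lists that passed, and the other lists as medians. miR-17-3p and miR-223-3p, which go against their lists, were chosen after their values were seen. Where a probe was not detected on any array of a group, its difference is given as "at least N-fold": the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest value among detected probes and the probe's own.

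The pipeline was tested on simulated data for FA 1 day versus control with 462 probes. With 60 probes changed per draw over 20 draws, 57.5% of probes changed by 1 on the log2 scale and 94.7% of those changed by 2 were recovered, 0.535% of the unchanged probes were called, and a list of 5 probes shifted by 0.6 was called in 18 of 20 draws. These draws had independent errors between probes, which real arrays do not have. They also changed many probes strongly at once, which eases the adjusted threshold. The shares are therefore not the power of this study where fewer probes change. In the data themselves 18 probes differed by at least 1 in this comparison and 0 passed.

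The groups, tests, lists, naming rule and other settings were fixed before the data were examined. The other settings tried were plain background subtraction with values under 1 set to 1, an offset of 16, median scaling, no normalization between arrays, the deposited ratio table (log2, with blanks at the column's lowest value), no filter on dim probes, only probes detected on all 9 arrays, detection at 50, an intensity trend with robust variances, array weights, the replicate number as a block, only the arrays of the 2 groups compared, and leaving out each array in turn with the values and tested probes kept. Added after seeing the data were the fit without both arrays that stand apart, an estimated correlation under each setting in which a list passed, single arrays left out for the viral, unnamed and small RNA probes, and a covariate made of the first principal component of the 42 spike-in control probes with a mean of at least 30.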

Results

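MicroRNAs (miRNAs), short RNAs that repress matching messenger RNAs, were measured in the olfactory bulb, the brain region that receives the axons of the nasal sensory neurons. The 8-week-old male ICR mice breathed formaldehyde, an irritant gas, at 3 ppm for 6 hours on 1 day (FA 1 day, n = 3 arrays) or on 7 days (FA 7 days, n = 3), or were kept without it (control, n = 3). Of 1027 mouse probes, between 398 and 520 were detected per array, and 462 were tested. Detected on all 3 arrays of a group were 400 mouse probes in control, 444 in FA 1 day and 378 in FA 7 days. The 378 is limited by FA 7 days replicate 3, which had 398, where replicates 1 and 2 had 481 and 468. Values are normalized log2 intensities, differences are given with their standard error (SE) from limma, and group values as mean ± SD.

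A pair of arrays stood apart from the other 7. Over the tested mouse probes, the root mean square deviation from the mean of those 7 (each array itself left out) was 0.913 on control replicate 2 and 0.682 on FA 7 days replicate 3, against 0.265 to 0.470 on the others. The spike-in control probes, which do not measure the tissue's RNA, deviated on the same arrays, by 0.899 and 1.10 against 0.215 to 0.522. Their values were placed by the curve of each array's miRNA probes, so they are not independent of the tissue RNA. FA 7 days replicate 3 also had the lowest median signal over background, 224, where the other 8 arrays had 287.5 to 441.

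**Figure D1:**
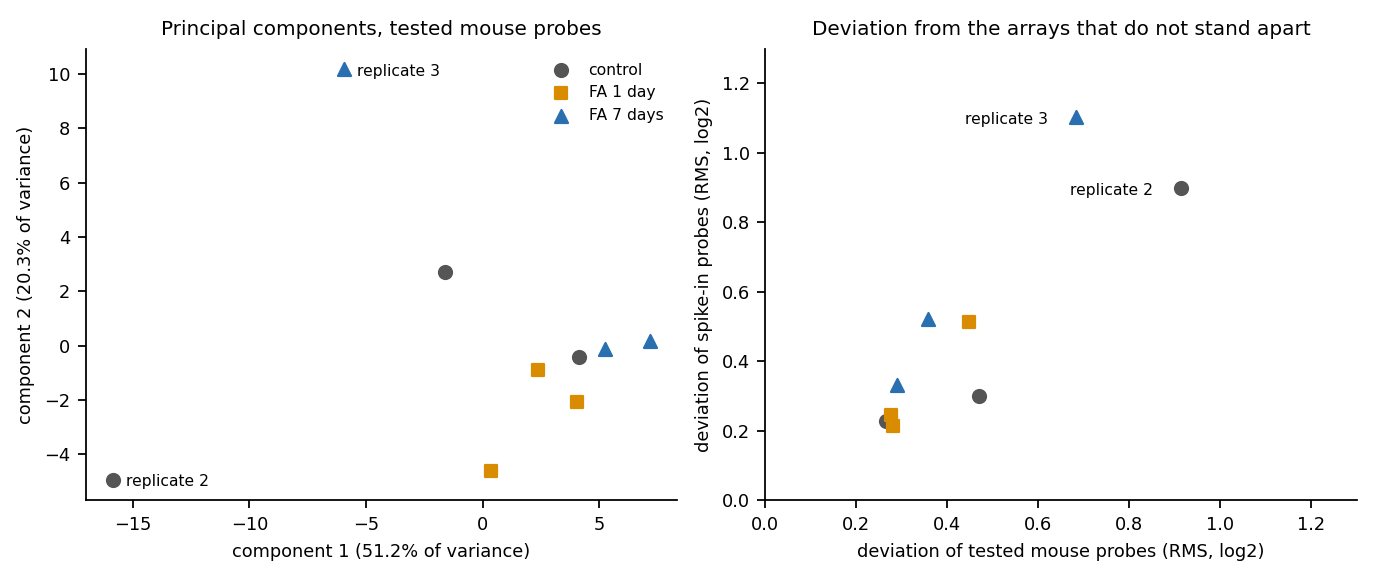
Left, the 9 arrays on the first and second principal components of the 462 tested mouse probes, which hold 51.2% and 20.3% of the variance. Right, each array's root mean square deviation (log2) over mouse probes against that over spike-in control probes; control replicate 2 (0.913 and 0.899) and FA 7 days replicate 3 (0.682 and 1.10) lie away from the other 7 arrays.

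The first comparison asks what a single day of formaldehyde does to bulb miRNAs. After 1 day the miR-17 cluster and its paralogs, known for their part in the proliferation of progenitor cells, lay higher as a group than in control, in 9 of 10 measured members, with a median log2 difference of 0.56. The group passed the test with a preset correlation (adjusted p = 0.0395) and did not with an estimated one (adjusted p = 0.860 with an estimated correlation). No single miRNA passed the test; among those with the smallest p, miR-199a-5p, miR-199a-3p and miR-214-3p, products of genes that share a host transcript, lay higher, and miR-146a-5p, which the NF-κB pathway induces and which restrains innate immune signalling, lay lower.

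The test of the miR-17 list was camera; with fry it had an adjusted p of 0.456, and 0 of its members passed when adjusted over the list alone. The estimated correlation between its members was 0.40, against the preset 0.01. Its members included miR-106a-5p, 0.63 ± 0.23 (SE) higher, and miR-19b-3p, 1.05 ± 0.53 higher (0.34 without control replicate 2); miR-17-3p was the 1 member that lay lower. Of its 14 listed miRNAs, 3 stand on other lists as well. The median deviation of its members from their 9-array means was 0.37, 0.16 and 0.19 on the FA 1 day arrays and -0.13, -0.59 and 0.01 on the control arrays, the lowest on control replicate 2, which stands apart. Without that array the median difference was 0.33 (adjusted p = 0.0925); the list also missed the threshold without control replicate 3 (0.150), FA 1 day replicate 1 (0.0699) or FA 1 day replicate 2 (0.0905), and passed it without both arrays that stand apart (0.0291, but adjusted p = 0.350 with an estimated correlation).

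With limma, 0 of 462 probes passed in FA 1 day versus control, while 29 had an unadjusted p under 0.05 (18 higher and 11 lower, 23.1 by chance), and the smallest adjusted p was 0.636. The 29 became 14 without FA 1 day replicate 1, 49 without FA 7 days replicate 3 and 67 without control replicate 3. Groups did not overlap for 69 probes, 14.9% against 10% by chance. The tested probes were chosen by detection in the real groups, which can raise this share in each comparison. The 3 miRNAs of the miR-199a and miR-214 genes were 1.20 ± 0.32 (miR-199a-5p, 7.49 ± 0.26 in control and 8.68 ± 0.67 after 1 day, n = 3 each), 0.96 ± 0.29 (miR-199a-3p, whose probe also matches miR-199b-3p) and 0.64 ± 0.22 higher (miR-214-3p). miR-199b-5p and miR-144-5p, the latter from a gene of red blood cells, were not detected on any control array and were at least 1.48-fold and at least 1.52-fold higher after 1 day. miR-205-5p, known from surface epithelia, was 1.03 ± 0.35 higher, and detected on 1 of 3 control arrays. miR-291b-3p (0.79 ± 0.21), miR-151-5p (0.68 ± 0.19), miR-3473, miR-871-3p and miR-31-5p completed the higher set, at 0.58 to 0.79. In the other direction, miR-146a-5p differed by -0.86 ± 0.26 (8.77 ± 0.43 in control and 7.91 ± 0.14 after 1 day), miR-204-3p by -0.89 ± 0.28, miR-320-3p by -0.59 ± 0.20, and miR-7a-5p, a miRNA of neurons and neuroendocrine cells, by -0.39 ± 0.16. miR-3104-3p (-1.50 ± 0.52) and miR-1943-3p (-1.59 ± 0.71) varied widely among the controls (SD 1.22 and 1.76). On control replicates 1, 2 and 3 miR-3104-3p lay at 8.44, 9.10 and 6.73, against 6.41 to 6.78 after 1 day. miR-1943-3p lay at 11.06, 9.48 and 7.54, against 7.60 to 7.93, and miR-1947-3p at 8.18, 8.19 and 7.02, against 6.97 to 7.07. These values thus differ among the controls, with replicate 3 near the exposed arrays. Without that control replicate 3 miR-3104-3p passed the test (-2.18, adjusted p = 0.0248). miR-324-3p was not detected on any FA 1 day array and was at least 1.42-fold lower; miR-361-3p, miR-341-3p, miR-1947-3p, miR-874-5p and miR-705 were lower by values from -0.87 to -0.63. Without control replicate 2, which stands apart, miR-3104-3p differed by -1.0, miR-324-3p by -0.38 (-0.66 with it), miR-361-3p by -0.41 (-0.69) and miR-874-5p by -0.32 (-0.63). Without control replicate 1, miR-1943-3p differed by -0.74 and miR-705 by -0.53 (-0.87 with it). Without control replicate 3, miR-1943-3p differed by -2.50 and miR-1947-3p by -1.15 (-0.76). Without FA 1 day replicate 4, miR-871-3p differed by 0.41 (0.72 with it).

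The other 15 lists did not pass after 1 day as tested here. With median scaling of the arrays the astrocyte and red blood cell lists passed (medians 0.37 and 0.36, both adjusted p = 0.0389), as they did without normalization (0.0453), and with all mouse probes the miR-183 cluster did (0.0228). Without both arrays that stand apart the neuron, oligodendrocyte and let-7 lists passed, with medians of -0.19, -0.44 and -0.40 (adjusted p = 0.0305, 0.0376 and 0.0232). None of the lists passed under these settings with an estimated correlation (adjusted p = 0.350 to 0.879 with an estimated correlation). The miR-183 cluster (miR-183, miR-96 and miR-182, known from sensory neurons and epithelia) lay higher in 5 of 5 members, with a median of 0.32 (adjusted p = 0.222). At an adjusted p of 0.305 were the miR-200 family, known for olfactory neurogenesis and epithelial identity (median 0.32), and astrocyte miRNAs (0.39). Red blood cell miRNAs (0.44, with 1 member passing when adjusted over the list alone) and vascular miRNAs (0.43, with 2) had the same value. So did the guanine-rich list (-0.06), a technical list of miRNAs that often light up on arrays without their target, not all of them rich in guanine. Neuron-enriched miRNAs had a median of -0.00 and oligodendrocyte miRNAs one of -0.19 (both 0.521), and inflammation and stress miRNAs 0.14 (0.722). At 0.876 were the imprinted Dlk1-Dio3 cluster (0.08), myeloid and lymphoid miRNAs (0.01), neuronal-activity miRNAs (-0.05) and the miR-29 and miR-30 families (0.04). The let-7 family (0.10, 0.904) and the muscle and surface epithelium list (0.15, 0.955) came last. For the Dlk1-Dio3, myeloid, let-7 and muscle lists the median and mean were positive while the test pointed down, and for the neuron and neuronal-activity lists the mean was positive (0.02 and 0.07) while median and test were not. Without control replicate 2 the medians were 0.16 for the astrocyte list, 0.03 for red blood cells, 0.18 for the miR-200 family, -0.44 for oligodendrocytes, -0.19 for neurons and -0.40 for let-7. Without control replicate 3 they were 0.48 for the miR-183 cluster and 0.52 for the miR-200 family, and without FA 1 day replicate 1 the latter had 0.18. The medians of the neuron, neuronal-activity, Dlk1-Dio3, myeloid, let-7 and muscle lists, all at most 0.15 in size, turned sign with 1 array or another left out.

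The second comparison asks what 7 days of exposure leave in the bulb. After 7 days miR-146b-5p, a relative of miR-146a that also restrains innate immune signalling, lay 0.77 ± 0.24 above control (8.77 ± 0.47 in control and 9.54 ± 0.05 after 7 days, n = 3 each), or 0.50 without control replicate 2, which stands apart. miR-21-5p, which rises in many inflamed tissues, lay 0.47 ± 0.19 higher. miR-210-3p, the miRNA best known from hypoxia, lay 0.48 ± 0.19 higher, and miR-133b-3p, a muscle miRNA, differed by -0.76 ± 0.30 (-0.41 without control replicate 2). None of these passed the test, nor did any list. The inflammation and stress list, which holds miR-146b-5p, miR-21-5p and miR-210-3p, had a median of 0.01, with 10 members higher and 7 lower.

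With limma, 0 of 462 probes passed in FA 7 days versus control, 21 had an unadjusted p under 0.05 (14 higher and 7 lower, 23.1 by chance) and the smallest adjusted p was 0.701. The 21 became 11 without control replicate 2, 66 without control replicate 3, and 12, 8 and 52 without FA 7 days replicate 1, 2 and 3. Groups did not overlap for 49 probes, 10.6% against 10% by chance. Higher after 7 days were also miR-1949 (0.65 ± 0.19), miR-151-3p (0.49 ± 0.16), miR-7b-5p (0.73 ± 0.24), miR-25-3p (1.13 ± 0.41, detected on 2 of 3 control arrays) and miR-24-3p (0.95 ± 0.39), and miR-181a-1-3p, miR-149-5p, miR-152-3p and miR-148a-3p at 0.58 to 0.88. miR-3104-3p (-1.41 ± 0.52), miR-204-3p (-0.75 ± 0.28), miR-1943-3p (-1.50 ± 0.71), miR-1947-3p (-0.94 ± 0.32), miR-324-3p and miR-361-3p, named for the first comparison, lay lower here too. Since both comparisons use the same control arrays, such repeats are not independent. miR-3098-3p, miR-296-5p and miR-299-5p (whose probe also matches miR-299b-5p) had values from -1.13 to -0.97, and miR-709 and miR-690 of -0.63 and -0.55. On control replicates 1, 2 and 3 miR-296-5p lay at 7.70, 8.39 and 6.65, against 6.38 to 6.84 after 7 days. miR-299-5p lay at 9.29, 9.71 and 7.81, against 7.50 to 8.33. These too differ among the controls. Without control replicate 3, which lay near the exposed arrays for miR-3104-3p, that probe passed here as well (-2.09, adjusted p = 0.0335). Without control replicate 2, which stands apart, the differences were 0.62 for miR-25-3p, 0.43 for miR-24-3p, 0.46 for both miR-149-5p and miR-152-3p (0.88 and 0.81 with it). In the other direction they were -0.91 for miR-3104-3p, -0.22 and -0.26 for miR-324-3p and miR-361-3p (-0.49 and -0.54), and -0.56 and -0.74 for miR-296-5p and miR-299-5p (-0.97 and -1.13). miR-1943-3p differed by -0.65 without control replicate 1 and by -2.41 without control replicate 3. miR-709 and miR-690 differed by -0.26 and -0.34 without FA 7 days replicate 3.

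Of the lists, the miR-183 cluster came closest after 7 days, lower in 5 of 5 members with a median of -0.36 (adjusted p = 0.0865). Myeloid and lymphoid miRNAs lay higher in 7 of 9 (median 0.77, adjusted p = 0.124), oligodendrocyte miRNAs in 5 of 5 (0.39, 0.128) and the let-7 family in 8 of 9 (0.63, 0.141). Without control replicate 2, which stands apart, the last 3 had medians of 0.24, 0.16 and -0.00 (adjusted p = 0.228, 0.693 and 0.869). Let-7 had 0.34 without FA 7 days replicate 1. The miR-183 cluster had -0.12 (0.433) without FA 7 days replicate 3, which also stands apart, and -0.19 (0.338) without control replicate 3. At 0.567 were the miR-200 family (-0.14), the miR-17 cluster (0.19), and the inflammation (0.01), vascular (0.13), muscle (0.03), astrocyte (0.62) and neuron (0.04) lists. The miR-29 and miR-30 families (0.11, 0.786), the guanine-rich (0.14), Dlk1-Dio3 (0.09) and neuronal-activity lists (-0.10, all 0.906) and the red blood cell list (-0.10, 0.982) followed. Mean and test pointed down for the muscle and guanine-rich lists, whose medians were positive, while the mean was positive (0.12) for the neuronal-activity list, and mean and test were positive for the red blood cell list. The miR-200 family had a median of 0.05 without FA 7 days replicate 3 and -0.29 without control replicate 2, the astrocyte list 0.10 without control replicate 2 and the neuron list 0.37 without FA 7 days replicate 3. The neuronal-activity, red blood cell, guanine-rich, muscle and neuron medians turned sign with 1 array or another left out. With median scaling the let-7 (adjusted p = 0.00171), myeloid (0.00344), astrocyte (0.0245), neuron (0.0260), miR-29 and miR-30 (0.0379) and oligodendrocyte lists (0.0441) passed, and all but the oligodendrocyte list did so without normalization too (adjusted p = 0.350 to 0.773 with an estimated correlation). With the deposited ratios the let-7 and myeloid lists did (both 0.00869), and with all mouse probes the miR-183, myeloid and oligodendrocyte lists (all 0.0453). The miR-183 cluster passed without control replicate 1 (0.01), FA 7 days replicate 1 (0.0108) or FA 7 days replicate 2 (0.0172), the myeloid and let-7 lists without control replicate 1 (both 0.01), and the miR-17 cluster (0.55) and the guanine-rich list (-0.26) without FA 7 days replicate 3 (both adjusted p = 0.0403). With an estimated correlation none of the lists passed under these settings or without these arrays (adjusted p = 0.332 to 0.908 with an estimated correlation). The miR-17 median was 0.03 without FA 7 days replicate 2.

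The last comparison asks whether longer exposure differs from shorter. After 7 days the miR-183 cluster lay lower as a group than after 1 day, in 5 of 5 measured members (median log2 difference -0.67), and so did the miR-200 family, in 6 of 8 (-0.37). Oligodendrocyte miRNAs lay higher as a group, in 4 of 5 members (0.60), as did myeloid and lymphoid miRNAs, in 8 of 9 (0.49), some of them near 0. These 4 groups passed the test with a preset correlation and none did with an estimated one (adjusted p = 0.506, 0.506, 0.517 and 0.506 with an estimated correlation, in that order). The miRNA with the smallest p was miR-146a-5p, at 7.91 ± 0.14 after 1 day and 9.11 ± 0.32 after 7 days (n = 3 each), a difference of 1.19 ± 0.26 that did not pass the test.

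The miR-183 cluster had an adjusted p of 0.000115 (camera, preset correlation), and an adjusted p = 0.506 with an estimated correlation and 0.319 with fry. The estimated correlation was 0.62, against the preset 0.01. The preset value treats the members as nearly independent, so its p overstates the evidence where they move together. Of its members, miR-183-5p differed by -0.76 ± 0.21 (12.56 ± 0.23 after 1 day and 11.81 ± 0.13 after 7 days), and miR-182-3p was not detected on any FA 7 days array and was at least 1.32-fold lower (log2 difference -0.77, or -0.51 without FA 1 day replicate 1); 2 of 5 passed when adjusted over the list alone. No member stands on another list. The median deviation from the 9-array means was 0.58, 0.21 and 0.21 on the FA 1 day arrays and -0.07, -0.23 and -0.69 on the FA 7 days arrays, the last being replicate 3, which stands apart. Without that array the median difference was -0.43 (adjusted p = 0.00864), and without both arrays that stand apart it had an adjusted p of 0.0226 (adjusted p = 0.684 and 0.558 with an estimated correlation).

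Oligodendrocyte miRNAs had an adjusted p of 0.0259, and an adjusted p = 0.517 with an estimated correlation, which was 0.49. miR-219-2-3p, from a hairpin known to promote the maturation of oligodendrocytes, was 0.58 ± 0.18 higher. miR-338-5p, from a hairpin known for the same role, was 0.70 ± 0.25 higher (0.43 without FA 1 day replicate 2). miR-219-5p was 0.72 ± 0.47 higher, and miR-23a-3p, the 1 member that lay lower, differed by -0.15 ± 0.24. When adjusted over the list alone 2 of 5 members passed, and 1 of the 5 stands on another list. The list missed the threshold without FA 7 days replicate 2 (adjusted p = 0.0728) and passed it without both arrays that stand apart (0.0226, but adjusted p = 0.508 with an estimated correlation).

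The miR-200 family and the myeloid and lymphoid list both had an adjusted p of 0.0355, and an adjusted p = 0.506 with an estimated correlation. Their estimated correlations were 0.13 and 0.11. In the miR-200 family miR-200b-5p differed by -0.96 ± 0.33 and miR-141-5p by -0.93 ± 0.31 (-0.59 without FA 7 days replicate 3). The 2 members that lay higher were miR-200a-3p (0.15 ± 0.16) and miR-429-3p (0.13 ± 0.22), and miR-200b-3p differed by -0.17 ± 0.30. In this family 0 members passed when adjusted over the list alone and 1 of 9 listed miRNAs is on another list. In the myeloid list miR-146a-5p, the 1 member passing when adjusted over the list alone, and miR-146b-5p (0.75 ± 0.24) led. miR-223-3p, a granulocyte miRNA, had the opposite sign (-0.88 ± 0.59). miR-142-3p (0.10 ± 0.73) and miR-150-5p (0.03 ± 0.24), counted as higher, lay near 0. A change in immune cells was not tested. In the myeloid list 4 of 10 listed miRNAs are on other lists. The miR-200 family missed the threshold without FA 7 days replicate 3 (0.159), FA 1 day replicate 1 (0.0737) or FA 1 day replicate 4 (0.0629), and the myeloid list without those arrays (0.122, 0.0848 and 0.112) or FA 7 days replicate 2 (0.0728); its median was 0.26 without FA 1 day replicate 4. Without both arrays that stand apart their adjusted p values were 0.190 and 0.0821.

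**Figure D2:**
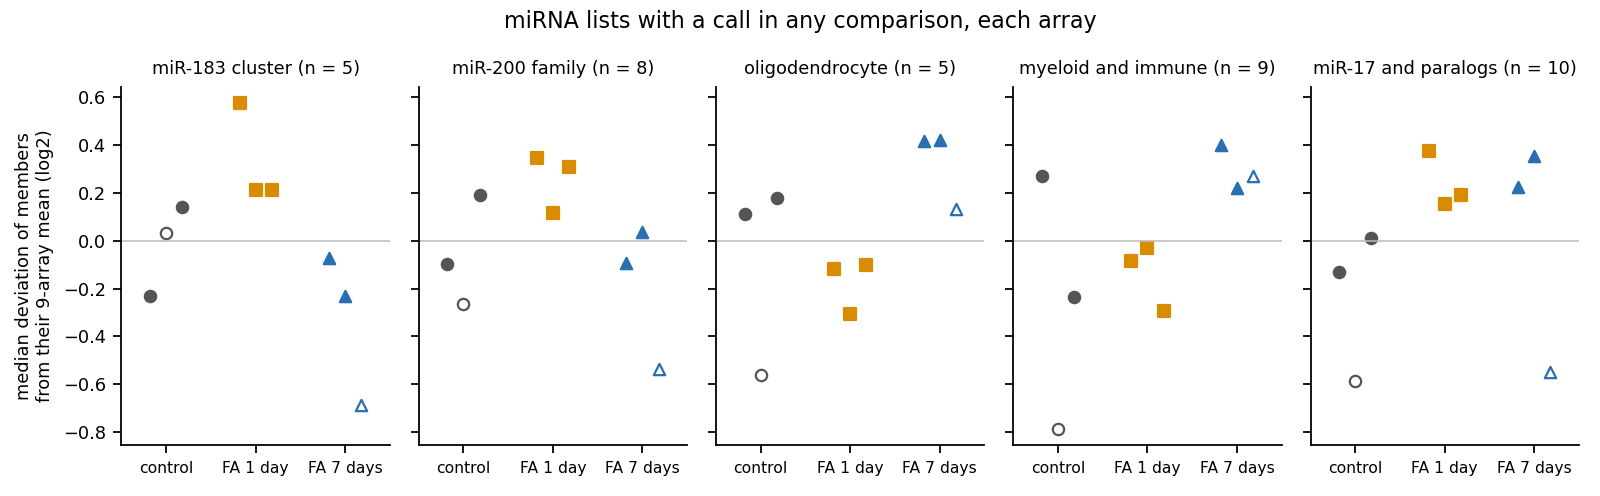
Median deviation (log2) of each list's tested members from their 9-array means, for 5 lists on the 9 arrays, by group; hollow markers are control replicate 2 and FA 7 days replicate 3. In the miR-183 cluster the FA 1 day arrays sit from 0.21 to 0.58 and the FA 7 days arrays from -0.69 to -0.07.

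With limma, 0 of 462 probes passed in FA 7 days versus FA 1 day, 38 had an unadjusted p under 0.05 (21 higher and 17 lower, 23.1 by chance; 23 without FA 1 day replicate 1) and the smallest adjusted p was 0.422. Groups did not overlap for 93 probes, 20.1% against 10% by chance, a share that the choice of probes by detection in the real groups can raise. With array weights, which give control replicate 2 and FA 7 days replicate 3 weights of 0.190 and 0.174, 23 probes passed, 17 higher and 6 lower. Besides miR-146a-5p, values were higher after 7 days for miR-1949 (0.81 ± 0.19), miR-221-3p, known from vessel walls (0.71 ± 0.19), let-7i-5p (0.71 ± 0.22), let-7g-5p (0.65 ± 0.23), miR-7b-5p (0.76 ± 0.24), and miR-125a-3p, miR-485-5p and miR-3096-3p at 0.56 to 0.63. Values were lower for miR-34c-5p, a p53-responsive miRNA (-0.87 ± 0.24), miR-199a-5p (-1.07 ± 0.32), miR-199a-3p (-0.82 ± 0.29), miR-151-5p, miR-291b-3p and miR-871-3p, all higher after 1 day than in control, and for miR-23b-3p (-0.75 ± 0.25). miR-199b-5p was not detected on any FA 7 days array and was at least 1.33-fold lower. miR-23b-3p differed by -0.45 without FA 7 days replicate 3, miR-199a-3p by -0.54 without FA 1 day replicate 1, and miR-871-3p by -0.45 without FA 1 day replicate 4 (-0.76 with it).

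**Figure D3:**
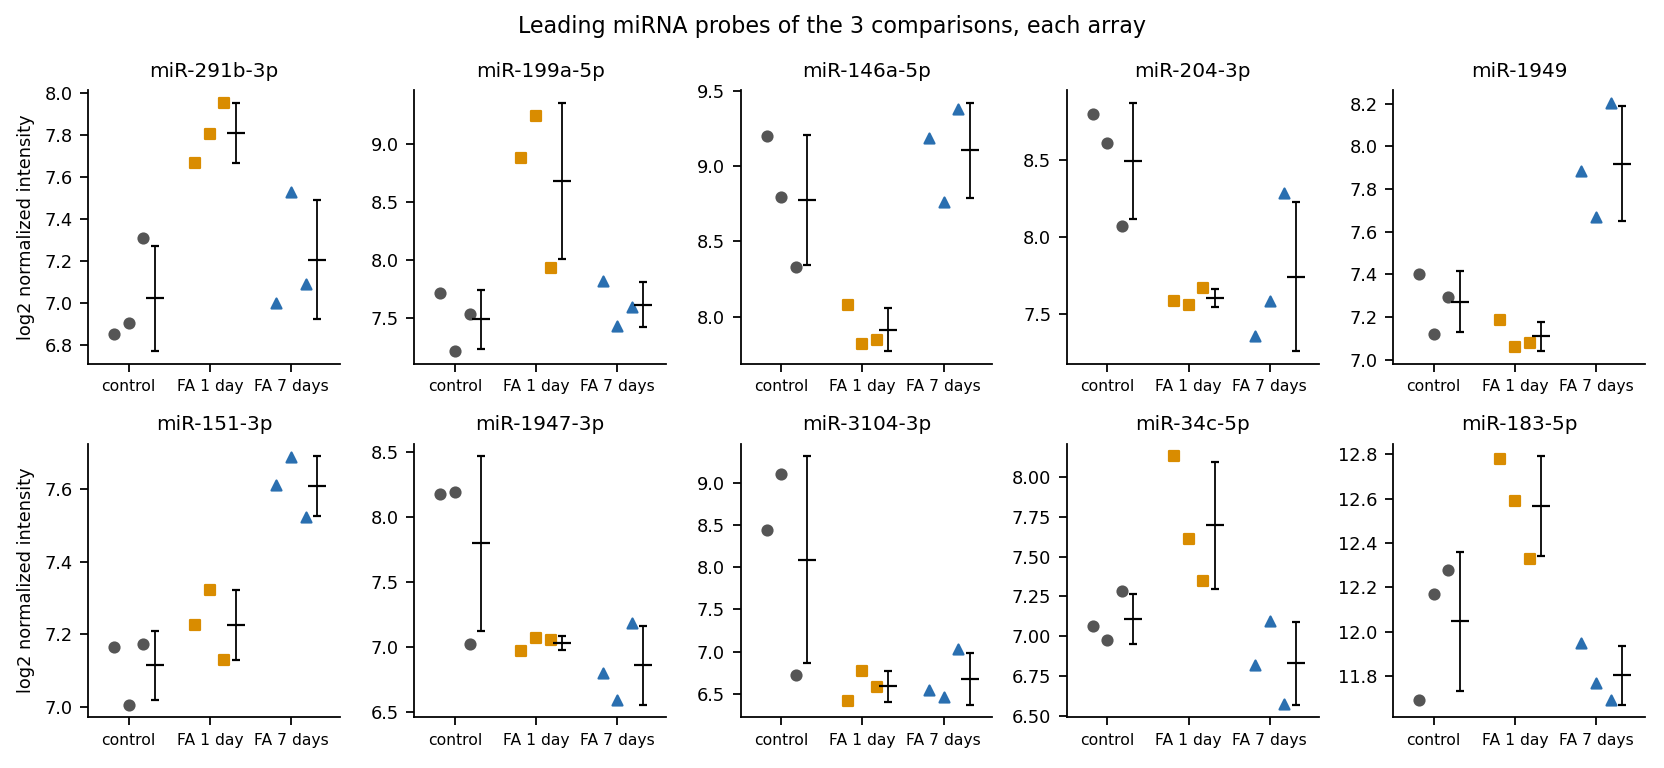
Normalized log2 intensity of 10 leading miRNAs on each array, by group; points are arrays (n = 3 per group) and bars the mean ± SD. miR-146a-5p sits at 8.77 ± 0.43 in control, 7.91 ± 0.14 after 1 day and 9.11 ± 0.32 after 7 days.

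The other 12 lists did not pass between 1 and 7 days as tested here. The let-7 family had a median of 0.20 (adjusted p = 0.133), neuron-enriched miRNAs 0.15 and the miR-17 cluster -0.25 (both 0.135). Red blood cell miRNAs had -0.12 (0.209), the guanine-rich list 0.11 (0.260) and the muscle and surface epithelium list -0.15 (0.454). Vascular miRNAs had a median of -0.33 (0.630) with 2 members passing when adjusted over the list alone, miR-221-3p higher and miR-199a-5p lower. Astrocyte miRNAs (0.01, 0.651), the Dlk1-Dio3 cluster (0.00, 0.751), inflammation and stress miRNAs (0.05, 0.751, 1 passing when adjusted over the list alone), the miR-29 and miR-30 families (0.06, 0.846) and neuronal-activity miRNAs (-0.14, 0.954) followed. The mean and test pointed down for the astrocyte list, the mean was -0.02 for the inflammation list, and mean and test pointed up for the neuronal-activity list. Without both arrays that stand apart the let-7 family and the neuron list passed, with medians of 0.50 and 0.35 (adjusted p = 0.00163 and 0.00354, but adjusted p = 0.243 and 0.398 with an estimated correlation). Both also passed with array weights (0.00916 and 0.00404), the deposited ratios (0.0436 and 0.00908), the spike-in component as a covariate (0.0230 and 0.0462) and without FA 7 days replicate 3 (0.0147 and 0.00864); the neuron list passed with median scaling (0.0414) and without normalization (0.0435), and the Dlk1-Dio3 cluster with array weights (0.0334). The miR-17 cluster passed without FA 7 days replicate 1 (0.0493) or 2 (0.0261), and the guanine-rich list without FA 7 days replicate 2 (0.0247). With an estimated correlation no list passed under any of these settings or without any of these arrays (adjusted p = 0.243 to 0.853 with an estimated correlation). Without FA 7 days replicate 3 the medians were 0.10 for the vascular list, -0.10 for the miR-17 cluster and -0.16 for the guanine-rich list. Let-7 had -0.11 and 0.02 without FA 7 days replicates 1 and 2. The Dlk1-Dio3, astrocyte, neuronal-activity, and miR-29 and miR-30 medians turned sign with 1 array or another left out.

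Across the 3 groups, limma's moderated F-test found 0 of 462 probes past the threshold, with 31 at an unadjusted p under 0.05 (from 11 without FA 1 day replicate 1 to 64 without control replicate 3) and a smallest adjusted p of 0.673; with array weights 8 passed, and without control replicate 3, 1 did. The differences of FA 1 day and FA 7 days from control had a Pearson r of 0.62 (Spearman rho 0.53) across the 462 miRNA probes, which are not independent replicates. Without control replicate 2, which stands apart, r was 0.36. Unchanged groups sharing these controls gave a mean r of 0.389 in 100 simulations, from -0.831 to 0.971, and 42 gave an r as large. The covariance was 0.107 against a simulated 0.0617, a difference of 0.0453, and 19 simulations were as large; 70.6% of probes had the same sign in both, against 64.4% simulated. No excess over unchanged groups was shown. With 3 control arrays a split of the controls leaves fewer than 2 in a part, and part of the r may come from the shared controls.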

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

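The tests against the spike-in control probes were chosen only after the results were seen. The 4 lists that passed between FA 1 day and FA 7 days stand out because the 2 exposures, set against the same control, differed by a test of the difference itself, with a preset correlation. With an estimated correlation none of the 4 passed (adjusted p = 0.517 for oligodendrocyte miRNAs and 0.506 for each of the others). Oligodendrocyte miRNAs had a median log2 difference of 0.60 (FA 7 days minus FA 1 day; 0.39 and -0.19 against control, or 0.16 and -0.44 without control replicate 2, which stands apart); with the array-wide trend of the spike-in control probes as a covariate their mean went from 0.49 ± 0.24 to 0.58 ± 0.21 (SE) and their adjusted p from 0.0259 to 0.00792 (adjusted p = 0.514 with an estimated correlation). Myeloid and lymphoid miRNAs had one of 0.49 (0.26 without FA 1 day replicate 4; 0.77 and 0.01 against control, the 0.77 being 0.24 without control replicate 2); with that covariate their mean went from 0.38 ± 0.31 to 0.44 ± 0.33 and their adjusted p from 0.0355 to 0.0525.

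The miR-183 cluster (-0.67) and the miR-200 family (-0.37), both known from sensory and epithelial cells, passed in neither exposure against control: their medians were 0.32 and 0.32 after 1 day (adjusted p = 0.222 and 0.305) and -0.36 and -0.14 after 7 (0.0865 and 0.567). Without FA 7 days replicate 3, which stands apart, the latter were -0.12 and 0.05, and the -0.67 and -0.37 were -0.43 and -0.30 (adjusted p = 0.00864 and 0.159). With the array-wide trend of the spike-in control probes as a covariate, the miR-183 mean difference went from -0.68 ± 0.23 to -0.60 ± 0.20 (SE). Its adjusted p was then 0.00199 (camera, preset correlation, but adjusted p = 0.514 with an estimated correlation, 0.506 without the covariate). At the preset correlation this 1 component did not remove the difference. Array effects stay open as its cause, since the list did not pass with an estimated correlation and spike-in values depend on the curve of the miRNA probes. For the miR-200 family the mean went from -0.42 ± 0.19 to -0.34 ± 0.16 and the call ended (adjusted p = 0.0617); why it ended was not tested, and the trend stays open there. Less muscle and surface epithelium in the dissection cannot be told apart from a change in the bulb, since that list of 5 had a median of -0.15 with a 95% interval (bootstrap over members) from -0.63 to 0.24. A difference caused by the length of exposure remains a hypothesis that may be followed up.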

How the results depend on the processing

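The fits without both arrays that stand apart and with the spike-in component, and an estimated correlation under other settings, were chosen after seeing the data; the rest was planned. Counts of lists past the threshold over the 3 comparisons, 5 as reported, were 2 with plain background subtraction, 14 with median scaling, 13 without normalization between arrays, 9 with all mouse probes, 1 with probes detected on all 9 arrays, 8 without both arrays, and 0 with an estimated correlation or fry; no list that passed under another setting did so there with an estimated correlation. They ran from 2 (without FA 1 day replicate 1) to 8 (without control replicate 1) with 1 array left out, and were 3 without FA 1 day replicate 4. Against the reported fit (0.06), median scaling and no normalization moved the median of all probes, FA 1 day minus control, to -0.09 and -0.11. The replicate block (the number in the labels) gave 3 lists and 0 probes in each comparison. The miR-17 cluster and the myeloid list were lost (camera, adjusted p = 0.143 and 0.167). Same-numbered arrays' deviations correlated from -0.58 to 0.33, and 1 of 8 arrays correlated best with its own number. No sign of pairing was seen, but so few arrays, including both that stand apart, cannot exclude that equal numbers shared a slide or day. Array weights gave 23 probes for FA 7 days versus FA 1 day and 8 for the F-test. Leaving out 1 array gave 0 to 1 probes for each exposure versus control (miR-3104-3p, without control replicate 3) and for the F-test (without control replicate 3), and 0 for FA 7 days versus FA 1 day; no other alternative gave a probe. The r of the 2 exposures ran from 0.36 (without control replicate 2) to 0.81 (without control replicate 3). Of the 24 alternatives, the miR-183 cluster passed in 22, oligodendrocyte miRNAs in 20, the miR-200 family and the myeloid list in 13 and the miR-17 cluster in 10, with no reversal. Of the 128 miRNA values that the rule for naming took, which include list members the text does not name, 124 kept their sign throughout. For the lists, the cause was not tested. Dim probes near the detection level limit what can be seen.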

Other observations

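The tests on the arrays that stand apart were chosen only after the result was seen; those on array weights, hairpin arms and splits were set before their results were seen. Outside the mouse miRNAs, chosen after their values were seen (as was leaving out arrays there), a probe for a miRNA of murine gammaherpesvirus, mghv-miR-M1-7-3p, was lower than control after 1 day (-2.30 ± 0.42, adjusted p = 0.00132 over 11 viral probes, limma) and after 7 days (-1.70 ± 0.42, adjusted p = 0.0159). With 1 array left out it passed after 1 day each time, and after 7 days missed the threshold without control replicate 1 (0.0633) or FA 7 days replicate 1 (0.113) or 2 (0.0929). How many of the 11 viral probes passed depended on the control arrays kept: 6 after 1 day and 4 after 7 days without control replicate 3, and 2 and 0 without control replicate 1. On control replicates 1, 2 and 3 mghv-miR-M1-7-3p lay at 9.59, 9.23 and 8.26. The unnamed probe that passed, given next, had the same order there (11.77, 10.99 and 9.79). No test here shows that virus was present, and binding of other RNA to these probes was not tested. Of 328 unnamed probes tested, limma passed 1 after 1 day (-3.34 ± 0.51, adjusted p = 0.0286), 0 after 7 days and 0 between the exposures; 41, 35 and 22 had an unadjusted p under 0.05 (16.4 by chance), with 34 and 25 lower than control and 18 of the 22 higher after 7 days than after 1. The 1 probe missed the threshold without control replicate 2 (0.0864), FA 7 days replicate 1 (0.0849) or FA 1 day replicate 1, 2 or 4 (0.186, 0.159 and 0.125), and the counts that passed were 23 after 1 day and 17 after 7 days without control replicate 3, 4 and 2 without control replicate 1, and 1 each without control replicate 2. At an unadjusted p under 0.05 the 41 became 26 and 78 without control replicates 1 and 3, and 22 and 21 without FA 1 day replicates 1 and 4. The 35 became 16 without control replicate 2 or FA 7 days replicate 1 or 2, 23 without FA 1 day replicate 1 and 71 without control replicate 3, and the 22 became 13 and 12 without FA 1 day replicates 1 and 2. Of 12 probes for other small RNAs, limma passed 0 in each comparison, with 0 at an unadjusted p under 0.05 (2 after 1 day and 1 after 7 days without control replicate 3).

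Control replicate 2 and FA 7 days replicate 3 stand apart in both mouse and spike-in probes. Their spike-in deviation was 1.72 and 2.11 times the highest of the other 7 arrays (1.72 for the smaller), as hybridisation or labelling would give. Spike-in values were placed by the curve of each array's miRNA probes, however, so the tissue RNA can move them too. The ratio alone therefore does not tell tissue RNA from hybridisation or labelling. Brightness does not account for control replicate 2, whose 317.25 lies within the other arrays' 287.5 to 441, while the 224 of FA 7 days replicate 3 lies below them. A difference of the mice, alone or in addition, stays open.

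The 23 probes that passed for FA 7 days versus FA 1 day with array weights may carry array effects that the weights leave in. With the same weights 31% of 42 spike-in probes had an unadjusted p under 0.05 (exact binomial 95% interval 17.6 to 47.1), against 27.5% of mouse probes. The interval counts the spike-in probes as independent, but they share the arrays, so it understates the uncertainty. Of the 10 splits of the 6 arrays 1, the real one, gave as many probes. The highest other gave 2, and the splits are too few for a share under 0.05. The tested probes were chosen by detection in the real groups, which can favour the real split.

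A hypothesis is that both arms of a hairpin change together, as they would if the hairpin's own level changed. Across 101 hairpins, which are not independent replicates, the arms' differences had an r of 0.313 (FA 1 day versus control; Spearman rho 0.20) and 0.313 (FA 7 days versus FA 1 day; rho 0.24), above 95% of shuffled pairings, which reached 0.167 and 0.165, but 0.114 for FA 7 days versus control (0.166; rho 0.09). The signs matched for 58, 56 and 57 hairpins. Within groups the arms' deviations correlated too, with r from 0.157 to 0.392 on single arrays, so the relation may reflect differences between samples apart from the exposure.

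Other splits of the 6 arrays number 10 for each pair of groups, too few for a share under 0.05. All splits used the probes tested for the real groups, which can favour the real one. A real count of 0 is reached by every split, so the 10 of 10 splits that gave as many probes past the threshold in each comparison decide nothing; the highest other gave 0, 73 and 0 for FA 1 day versus control, FA 7 days versus control and FA 7 days versus FA 1 day. Probes at an unadjusted p under 0.05 numbered 29, 21 and 38 against 42, 164 and 19 in the highest other, with 2, 4 and 1 splits giving as many. Lists numbered 1, 0 and 4 against 5, 4 and 3, with 8, 10 (again against a 0) and 1 splits giving as many. The split with 73 probes set control replicates 1 and 2 and FA 7 days replicate 3 against the rest, which points to a structure of the samples. For the F-test's 0 probes the 100 of 100 splits that gave as many decide nothing either (highest other 18). For its 31 probes at an unadjusted p under 0.05, 19 of 100 splits gave as many (highest other 113), so for that count chance is not excluded.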
